A study of Mus musculus with 30 samples.

How the data were processed

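RNA of KH2 mouse embryonic stem cells was measured on 30 Affymetrix mouse genome arrays, 1 array per sample, at 8 times from 8 h to 72 h. Per the labels' protocols, the cells were grown on feeder fibroblasts, RA was used at 0.3 uM, cells were replated for 30 minutes on gelatin before lysis, and 200 ng of RNA was labelled with biotin. The labels describe that replating step in 2 ways, with RNA taken from the adhered cells or from the cells of the medium drawn off, and the values do not settle which was done. The values are log2 intensities, normalised between arrays by the authors before deposit. The method of background correction, probe summary and normalization is not stated, and per the submitters' processing notes limma 3.8.3 was used. The range of the values and the near equality of the quartiles across arrays were checked: lower quartiles lay between 4.73 and 4.85, medians between 6.34 and 6.39 and upper quartiles between 8.56 and 8.70. No pair of arrays within a group held identical values, out of 48 pairs.

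Of 45101 probe sets, 64 controls were left out, 13 of which carry a gene symbol. Another 9160 probe sets with no symbol and 932 with several were left out, and 34945 with 1 symbol remained. Where a gene had more than 1 probe set, as 9010 genes had, the one with the highest mean over all arrays was kept, which gave 18193 genes. The 13 controls with a symbol entered an early version of the fit in error and were then removed, as the plan required. No filter on dim genes, no pseudocount and no further normalization was applied.

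Genes were tested with limma 3.58.1 in R 4.3.3 (linear model on the 8 time groups, empirical Bayes variance, no block), in 1 fit of all arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided, and counts at a log2 change of at least 1 are given beside the main comparisons, which are 12 h, 24 h and 72 h against 8 h. The other times against 8 h and each pair of neighbouring times were tested in the same fit. A moderated F test covered all times. Named genes followed a rule. In each main comparison they are the 10 largest rises and 10 largest falls among called genes whose later arrays all lie beyond all earlier arrays, and in each other comparison the 3 largest of each. Of each list, up to 4 measured members with the largest change may be named, and any member of the RA and Hox lists.

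The 23 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation beside it, and p-values were adjusted over the lists within a comparison. At the main comparisons 33 list tests passed, and 7 passed with an estimated correlation. List members missing from the single-gene probe sets were not counted as measured. Hox onset was the first time with a called rise of at least 1 log2, and its relation to paralogue number was tested with Spearman's rho and 100000 permutations. The mean log2 of the embryonic fibroblast list was compared with exact permutation tests. The lists, tests, comparisons, naming rule and most alternatives were set before the data were examined.

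The array sets were found in the data, and the labels give no date. The spike-in difference that defines them (BioDn 5' minus BioC 5') was chosen after 20 differences between spike-in probe sets had been tried. Of these, 19 separate arrays A to C from D to F at 12 h and 24 h, and 6 give the same 2 sets at their widest gap. The separation at 12 h and 24 h is therefore partly by construction. Fits with the array set as a block, within set 1, within set 2, and the 72 h against 12 h comparison within set 2 were chosen after seeing the data.

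Alternatives covered centring or quantile normalising the arrays again, leaving out dim genes (below the 30th percentile), the mean of all probe sets of a gene, leaving out probe set types that can cross-hybridise, another variance prior, array weights, only the groups compared, only arrays A to C or D to F, the replicate letter as a block, each array left out in turn, and other definitions of onset and fibroblast level. The probe types called cross-hybridising were taken by a letter before _at in the probe set name. They include _a_at sets, whose letter can mark several transcripts of 1 gene. A change lost without that type need not come from cross-hybridisation. A planned pseudocount alternative was not run because the values are log2 already. The fit was tested on simulated data with 200 genes shifted per comparison. At 12 h against 8 h it called 71.6% of genes shifted by 0.5 log2, 95.5% at 1 and 100% at 2, with 10 unchanged genes called and 0 unchanged lists passing camera. At 72 h against 8 h it called 67.2%, 92.5% and 100%, with 9 unchanged genes called. The simulated noise was independent for each gene and array, with no difference between array sets. These false calls therefore say nothing about correlated genes or about the array sets.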

Results

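KH2 mouse embryonic stem cells, a line grown on a layer of feeder fibroblasts, were followed through a course of retinoic acid (RA), the vitamin A derivative that acts through nuclear receptors and patterns the embryo. RNA was hybridised to 30 Affymetrix mouse arrays, with 3 arrays each at 8 h, 16 h, 36 h, 48 h, 60 h and 72 h and 6 arrays each at 12 h and 24 h. The labels call the 8 h arrays baseline and the later ones retinoic acid, and they do not state whether RA was present at 8 h. Of 45101 probe sets, 34945 carried 1 gene symbol, and these gave 18193 genes with 1 probe set each. Array medians lay between 6.34 and 6.39 log2 and lower quartiles between 4.73 and 4.85, and the number of arrays limits the precision. The values carry no detection calls, so where the lower of 2 means lies under 4.73 the change is a lower bound, written as "at least", and has no place in an order by size. Changes are log2 differences between group means, with the standard error (SE) of the limma fit. P-values measure only the spread between these samples, since the labels do not say that arrays came from separate cultures.

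The 12 h and 24 h arrays differed by letter, A to C against D to F. At 12 h, the median of the measured members of the anterior Hox list was higher by 1.26 in D to F than in A to C, that of the central Hox list by 0.83, and that of the endoderm list by 0.43, while the glycolysis list had a median difference of -0.49. At 24 h these differences were 0.53, 0.49, 0.41 and -0.19. By limma, 6781 genes differed between the letters at 12 h (2976 higher and 3805 lower in D to F) and 5826 at 24 h (2337 higher and 3489 lower). The bacterial spike-in controls BioDn and BioC, added in fixed amounts, separated the same arrays and placed every other time on 1 side. Their log2 difference was 0.99 to 1.07 in 12 arrays (set 1: 8 h, 16 h and A to C) and 1.34 to 1.63 in 18 arrays (set 2: D to F and all arrays from 36 h on). Controls of RNA and labelling followed that split in part. The probe set of the B2 repeat lay at 14.60 to 14.75 in set 1 and 14.95 to 15.07 in set 2. That of the 5' end of 18S rRNA lay at 10.08 to 11.12 in 12 h A to C and 8.14 to 8.79 in 12 h D to F (9.03 to 10.53 and 7.99 to 8.35 at 24 h). Over all arrays its ranges overlapped, at 9.03 to 11.12 in set 1 and 7.99 to 9.17 in set 2. Those of the Dap labelling control, 9.94 to 10.77 and 10.76 to 11.96, also overlapped. The list differences between the letters run along with the spike-in, B2 and 18S controls, and the values do not separate them. Each comparison of 8 h or 16 h with 36 h or later therefore spans both sets, and values from a fit with the array set as a block, or from arrays of 1 set, stand beside the results they change. The block is estimated only from 12 h and 24 h, which hold both sets, and is taken as constant over the course. Between those times the set difference changed in 3495 genes by limma's interaction test. Block values that span both sets therefore rest on an assumption and are not corrected values.

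**Figure D1:**
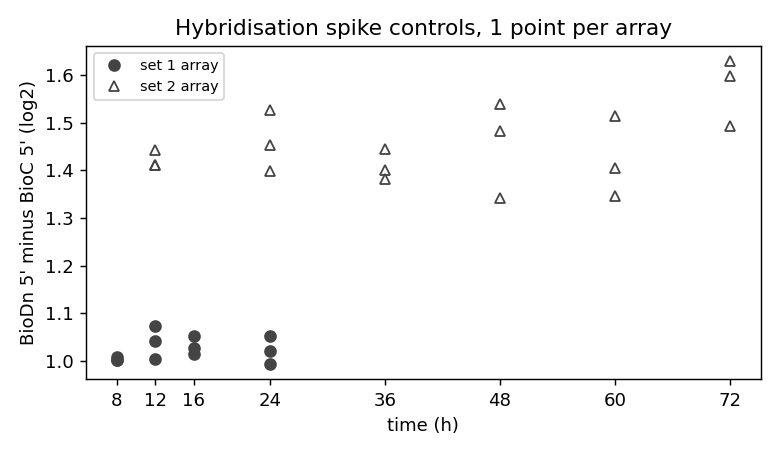
Difference between the BioDn and BioC spike-in probe sets (log2, y axis) on each of the 30 arrays against time (h, x axis). The 12 arrays of set 1 lie between 0.99 and 1.07 and the 18 arrays of set 2 between 1.34 and 1.63, and 12 h and 24 h hold arrays of both.

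Over the whole course, 13816 of 18193 genes (75.9%) passed limma's F test across the 8 times, and 13112 passed with the array set as a block.

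**Figure D2:**
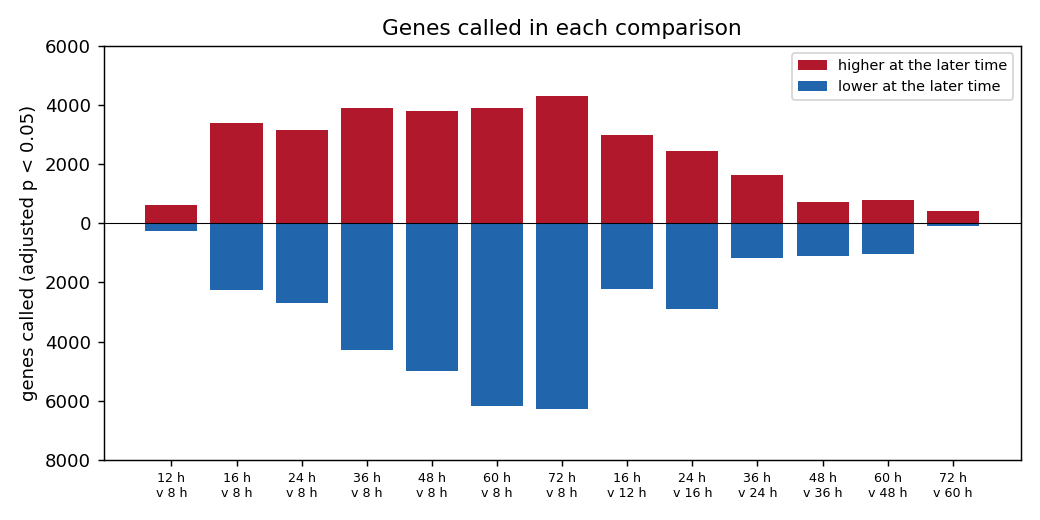
Genes called higher (red) and lower (blue) by limma in each of 13 comparisons, as a count of genes. Against 8 h the total runs from 901 genes at 12 h to 10601 at 72 h.

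The comparison of 12 h with 8 h asks which genes first departed from the baseline. Genes of the Hox clusters, whose transcription factors set position along the head-to-tail axis, led the rises. Hoxb6, on chromosome 11, rose from 6.35 ± 0.40 (SD, n = 3) to 8.63 ± 1.20 (SD, n = 6), a change of 2.29 ± 0.43 (SE, limma adjusted p = 0.0019). Hoxb3, Hoxa5, Hoxb2, Hoxb5, Hoxb1 and Hoxa3 rose by 1.76, 1.71, 1.61, 1.59, 1.44 and 1.42. Zfp703, a zinc finger co-repressor, rose by 1.66 ± 0.18 (SE, limma adjusted p = 3.7e-06), and Gpm6a, a membrane glycoprotein of neurons, by at least 1.44 ± 0.24 (SE, limma adjusted p = 0.00062). Sox1, a transcription factor of the early neural plate, rose by 1.77 ± 0.52 (SE, limma adjusted p = 0.047). Its call ended when any of the 8 h arrays or 12 h D, E or F was left out, with a change of 1.5 to 1.95, and its change was 0.77 with the array set as a block and 0.55, not called, in set 1 alone. In each of these genes, all 12 h arrays lay above all 8 h arrays. The other probe set of Gpm6a was called higher too, while no other probe set of Hoxb3, Hoxa5, Hoxa3, Zfp703 or Sox1 was called. In a fit of the 8 h and 12 h arrays alone, Zfp703 and Gpm6a stayed called and the Hox genes named here and Sox1 did not, and without 8 h C the calls of Hoxa5 (1.62) and Hoxa3 (1.33) ended. In the fit with the array set as a block, the changes of Hoxb6, Hoxa5 and Hoxa3 were 1.5, 0.97 and 0.84. Hoxa3 was also not called with the mean of its probe sets (0.55) or without probe types that can cross-hybridise (0.71).

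Among the falls from 8 h to 12 h, Ntn1, the secreted guidance cue netrin-1, fell by 1.03 ± 0.09 (SE, limma adjusted p = 2.1e-07). The other probe set of Ntn1 was not called. Msc, a repressor of the basic helix-loop-helix class, fell by 0.97 ± 0.17 (SE, limma adjusted p = 0.00084). Dmtn, an actin-bundling protein, fell by 1.09 ± 0.16 (SE, limma adjusted p = 0.00021) on an _a_at probe set. Another probe set of Dmtn, used where that type was left out, gave -0.10 and was not called. All 12 h arrays lay below all 8 h arrays for these genes and for the other 7 falls of the rule, from -1.23 in Notch4, a Notch receptor, to -0.93 in Fam167a. Notch4, Fabp3 and Anxa8 each lost the call without any of the 8 h arrays, with -1.09 to -1.35 for Notch4, -0.86 to -1.04 for Fabp3 and -1.03 to -1.14 for Anxa8. They also lost it without 12 h E or 12 h F, with -1.08 and -1.07 for Notch4, -0.86 and -0.84 for Fabp3 and -0.92 and -1.02 for Anxa8, and Fabp3 (-0.82) and Anxa8 (-0.99) without 12 h D. In a fit of the 8 h and 12 h arrays alone, Ntn1, Msc and Dmtn stayed called and the other 7 did not. Under the block for array set, Notch4 had -0.73, Fabp3, a fatty acid carrier, had -0.44, and Anxa8, a calcium-dependent membrane-binding protein, had -0.57 and was not called. Ephx2, Ldhb, Tcl1 and Fam167a had -0.66, -0.56, -0.64 and -0.61 under that block, against -1.19, -1.08, -0.98 and -0.93 without it.

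Crabp2, which carries RA to its receptors in the nucleus, rose by 1.21 ± 0.14 (SE) from 8 h to 12 h. The retinoic acid list rose, with 5 of 24 measured members higher and 0 lower (6 and 0 adjusted over the list alone), a median change of 0.15 and a camera adjusted p of 0.00297. It had adjusted p = 0.237 with an estimated correlation, 0.126 with the array set as a block and 0.0611 in set 1 alone. Anterior Hox genes (paralogue groups 1 to 4) rose, with 7 of 10 members higher and 0 lower (9 and 0 adjusted over the list alone), a median of 1.23 and a camera adjusted p of 3.81e-10. The median was 0.72 with the array set as a block, and adjusted p = 0.231 with an estimated correlation. Central Hox genes (groups 5 to 8) rose, with 3 of 9 higher and 0 lower (4 and 0 adjusted over the list alone), a median of 0.39 and a camera adjusted p of 0.000241. That list had adjusted p = 0.237 with an estimated correlation and 0.121 in set 1 alone. Posterior Hox genes (groups 9 to 13) had 1 of 14 members higher and 0 lower, also adjusted over the list alone, and a camera adjusted p of 0.485. Pluripotency genes fell, with 6 of 31 lower and 0 higher (10 and 1 adjusted over the list alone), a median of -0.18 and a camera adjusted p of 0.000161 (adjusted p = 0.274 with an estimated correlation). Trh, the precursor of thyrotropin-releasing hormone, fell by 0.83 within that list.

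Partner proteins of Hox factors, the TALE class, rose at 12 h, with 3 of 8 members higher and 1 lower, also adjusted over the list alone, a median of 0.36 and a camera adjusted p of 0.0248. The list had adjusted p = 0.237 with an estimated correlation, 0.0767 with the array set as a block and 0.408 in set 1 alone, where its median was 0.16. Pbx3, of this class, rose by 0.58. Endoderm genes had 1 of 26 higher and 0 lower (2 and 0 adjusted over the list alone), a median of 0.25 and a camera adjusted p of 0.00322. That value was adjusted p = 0.510 with an estimated correlation and 0.689 with the array set as a block, where the median was 0.00. Embryonic fibroblast genes, markers of feeders, had 1 of 30 higher and 0 lower, also adjusted over the list alone, a median of 0.35 and a camera adjusted p of 0.000684, against adjusted p = 0.550 with an estimated correlation and 0.0767 with the array set as a block. In set 1 alone 9 of 30 fibroblast genes were higher and 1 lower, with a median of 0.25 and a camera adjusted p of 0.00159. Immediate early genes, which answer growth signals within minutes, had 2 of 17 lower and 0 higher (3 and 0 adjusted over the list alone), a median of -0.13 and a camera adjusted p of 0.0185 (adjusted p = 0.447 with an estimated correlation). In set 1 alone 10 of 17 were lower and 1 higher, with a median of -0.27 and a camera adjusted p of 0.000100, and with arrays D to F alone the test pointed upward (median -0.0931, adjusted p = 0.862). Without 12 h B that list had a median of -0.12, without 12 h C -0.08, and neither was called. Atf3, a stress-induced transcription factor, fell by 0.67, a call that ended without 8 h B (-0.54).

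The other 15 lists did not pass camera at 12 h. Its adjusted p was 0.749 for formative and primed epiblast, 0.655 for neural and hindbrain, 0.615 for mesoderm, 0.335 for trophoblast, 0.650 for the two-cell-like state, 0.331 for germ cell, 0.149 for cell cycle and for the p53 response, 0.213 for heat shock and unfolded protein, 0.481 for Nodal, BMP and TGF-beta and for housekeeping reference, 0.918 for Wnt, FGF and hedgehog, 0.749 for glycolysis and 0.0647 for cholesterol synthesis. Foxc1 and Foxc2, mesoderm transcription factors, rose by at least 1.32 and by 0.73, and both lost the call in a fit of the 8 h and 12 h arrays alone, Foxc2 also without 8 h C (0.54). Sox4, of the formative list, rose by 0.82, a call that ended with the mean of its probe sets (0.39). In the neural list the median was -0.01 with a mean of 0.11 and an upward test, in the two-cell-like list the median was -0.02 with a mean of 0.05 and a downward test, and in the Nodal list the median was 0.03 with a mean of -0.01 and a downward test. In set 1 alone, 9 of 19 glycolysis genes were higher, with a median of 0.16 and a camera adjusted p of 7.38e-06, against a median of -0.06 in all arrays. With arrays D to F alone the glycolysis list passed downward (median -0.35, adjusted p = 0.00439). Cholesterol synthesis genes had a median of 0.17, and passed downward with the array set as a block (-0.0797, adjusted p = 0.0367) and upward with arrays D to F alone (0.38, adjusted p = 4.87e-06). They also passed upward in a fit of the 8 h and 12 h arrays alone (adjusted p = 0.0148), with the mean of all probe sets (0.0470), and without 8 h C (0.0289), 12 h A (0.0158), 12 h B (0.0318) or 12 h C (0.0237). With arrays D to F alone, posterior Hox, formative and trophoblast genes passed upward (adjusted p = 0.0157, 0.0142 and 0.0157) and p53 response genes downward (0.0390), the latter also with the mean of all probe sets (0.04995).

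Between 8 h and 12 h, limma called 901 of 18193 genes, 631 higher and 270 lower, and 38 of them changed by at least 1 log2, of which 32 were higher and 6 lower. Without 8 h A the count was 411, without 8 h B 351 and without 8 h C 320, while it was 1923 with the array set as a block, 713 of them among the 901, and 4324 in set 1 alone.

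The comparison of 24 h with 8 h describes the first day. Crabp2 rose from 9.02 ± 0.07 (SD, n = 3) to 12.85 ± 0.24 (SD, n = 6), a change of 3.83 ± 0.14 (SE, limma adjusted p = 3.3e-16). Hoxb6 rose by 4.08 ± 0.43 (SE, limma adjusted p = 5.2e-08) and Hoxc5, on chromosome 15, by at least 3.93 ± 0.34 (SE, limma adjusted p = 2.5e-09). Hoxa5, Hoxb3, Hoxb2, Hoxb9 and Hoxa9 rose by 3.14, 3.03, 2.98, 2.97 and 2.95, and Hoxa9 had a change of 1.59 with the array set as a block. Sox1 rose by 3.43 ± 0.52 (SE, limma adjusted p = 1.2e-05) and Zfp703 by 2.93 ± 0.18 (SE, limma adjusted p = 4.7e-12), although 1 of the other 2 probe sets of Zfp703 was called lower. The other probe sets of Sox1 and Hoxa9 were not called, while those of Hoxc5, Hoxa5 and Hoxb3 were called higher too.

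Inhbb, a subunit of activin and inhibin, fell most by 24 h. Its change was -2.92 ± 0.46 (SE, limma adjusted p = 2.0e-05). Nrp2, a receptor for semaphorins, fell by 2.09 ± 0.26 (SE, limma adjusted p = 9.9e-07), Notch4 fell by 2.05 and Tcl1, an Akt coactivator abundant in stem cells, fell by 1.98. Otx2, a homeodomain factor of the epiblast and forebrain, fell by 2.04 ± 0.45 (SE, limma adjusted p = 0.00094), with -1.19 in the fit with the array set as a block. Slc15a1, a peptide transporter, fell by at least 1.96 with -1.15 in that fit, and Enox1, Rgcc, Nphs1 and Eva1a had changes from -1.94 to -1.79, the last -1.19 in that fit. All 24 h arrays lay beyond all 8 h arrays for each of these 10 rises and 10 falls.

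At 24 h the retinoic acid list rose, with 12 of 24 members higher and 2 lower (12 and 3 adjusted over the list alone), a median of 0.27 and a camera adjusted p of 0.000342 (adjusted p = 0.0651 with an estimated correlation). Nr2f1, an orphan nuclear receptor, rose by 2.29, Stra6, a retinol transporter, by 1.30 and Stra8, a germ cell gene induced by RA, by 1.25. Anterior Hox genes rose, 9 of 10 higher and 0 lower, also adjusted over the list alone, with a median of 2.48, a camera adjusted p of 6.41e-12 and adjusted p = 0.0485 with an estimated correlation. Central Hox genes rose, 7 of 9 higher and 0 lower, also adjusted over the list alone, with a median of 1.67 and a camera adjusted p of 5.90e-06 (adjusted p = 0.0796 with an estimated correlation). The median of central Hox genes was 1.08 with the array set as a block. Posterior Hox genes had 7 of 14 higher and 0 lower (7 and 3 adjusted over the list alone), a median of 0.25 and a camera adjusted p of 0.0404, which was adjusted p = 0.308 with an estimated correlation. That call ended without 8 h B (median 0.21), 8 h C (0.28), 24 h D (0.32) or 24 h F (0.35) and where cross-hybridising probe types were left out (0.17). TALE cofactors rose, 6 of 8 higher and 0 lower (6 and 1 adjusted over the list alone), with a median of 0.67, a camera adjusted p of 0.000889 and adjusted p = 0.0459 with an estimated correlation, Pknox2 by 2.82 and Meis1 by 2.66.

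Pluripotency genes fell by 24 h, with 24 of 31 lower and 1 higher, also adjusted over the list alone, a median of -0.57, a camera adjusted p of 2.14e-12 and adjusted p = 0.0459 with an estimated correlation. Esrrb, an orphan receptor that maintains the stem cell state, fell by 1.51, Dppa3 fell by 1.40 and Nr0b1 fell by 1.39. Fibroblast genes rose beside them, with 8 of 30 higher and 0 lower, also adjusted over the list alone, a median of 0.51 and a camera adjusted p of 0.00142 (adjusted p = 0.413 with an estimated correlation). In set 1 alone 14 of 30 fibroblast genes were higher and 0 lower, with a median of 0.28 and a camera adjusted p of 0.00456, and with the array set as a block the median was also 0.28. Endoderm genes had 11 of 26 higher and 1 lower (12 and 1 adjusted over the list alone), a median of 0.52 and a camera adjusted p of 0.00268, with adjusted p = 0.413 with an estimated correlation. Foxa2 and Sox17, transcription factors of endoderm, rose by 1.31 and 1.19. With the array set as a block, Sox17 had a change of 0.63, and the endoderm list had a median of 0.10 and adjusted p = 0.0984, and in set 1 alone 0.12 and 0.120. Cholesterol synthesis genes had 10 of 13 higher and 0 lower (11 and 0 adjusted over the list alone), a median of 0.55 and a camera adjusted p of 0.000252, against adjusted p = 0.413 with an estimated correlation. In set 1 alone that list had a median of 0.12 and adjusted p = 0.0905. Genes of the p53 response had 8 of 16 higher and 1 lower (9 and 1 adjusted over the list alone), a median of 0.21 and a camera adjusted p of 0.0141 (adjusted p = 0.165 with an estimated correlation). Btg2, an antiproliferative p53 target, rose by 0.67, and the list had a median of 0.14 and adjusted p = 0.0694 without cross-hybridising probe types and 0.15 and 0.0619 with arrays A to C alone.

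The other 13 lists did not pass camera at 24 h. The adjusted p was 0.311 for formative and primed epiblast, 0.0809 for neural and hindbrain and for immediate early, 0.192 for mesoderm, 0.0913 for trophoblast, 0.570 for the two-cell-like state, 0.109 for germ cell and for cell cycle, 0.894 for heat shock and unfolded protein, 0.154 for Nodal, BMP and TGF-beta, 0.518 for Wnt, FGF and hedgehog and for housekeeping reference, and 0.452 for glycolysis. Members moved both ways in several of them. In the neural list 12 of 28 rose and 5 fell (12 and 7 adjusted over the list alone), with Zic1 and Irx3, neural transcription factors, up by at least 1.59 and by 1.56. In the Wnt list 6 of 23 rose and 6 fell (6 and 8 adjusted over the list alone), and Etv4, an FGF target, fell by 1.30. Bmp4, a ligand of the Nodal and BMP list, fell by 1.34, and Egr1, an immediate early gene, rose by 1.25. In the Wnt list the median was -0.05 with a mean of 0.01 and a downward test, in the glycolysis list the median was 0.03 with a mean of -0.01 and an upward test, and in the heat shock list the median of -0.05 stood beside an upward test. Cell cycle genes had 4 of 25 lower and 1 higher, also adjusted over the list alone, and passed with the array set as a block (median -0.14, adjusted p = 0.0386). Glycolysis genes also passed there, with a median of 0.18 and adjusted p = 0.0442, and germ cell genes passed in set 1 alone, with a median of 0.33 and adjusted p = 0.00456. Immediate early genes passed upward with arrays D to F alone (adjusted p = 0.00824), with the mean of all probe sets (0.00410), without cross-hybridising probe types (0.0220) and without 24 h C (0.0372). Neural genes passed upward with arrays D to F alone (adjusted p = 0.00654), with the mean of all probe sets (0.0427) and without 24 h A (0.0437) or 24 h C (0.0372). Nodal, mesoderm and trophoblast genes passed upward with arrays D to F alone (adjusted p = 0.00704, 0.0374 and 0.0201), trophoblast genes also in a fit of the 8 h and 24 h arrays alone (0.0215), and germ cell genes with the mean of all probe sets (0.0427).

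Between 8 h and 24 h, limma called 5849 genes, 3146 higher and 2703 lower, and 478 changed by at least 1 log2, of which 392 were higher and 86 lower. With the array set as a block 7135 were called, 4994 of them among the 5849.

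The comparison of 72 h with 8 h describes the end of the course. Nr2f1 rose from 4.93 ± 0.22 to 11.10 ± 0.30 (SD, n = 3 each), a change of 6.17 ± 0.39 (SE, limma adjusted p = 8.1e-13). Fbn2, a microfibril protein of the extracellular matrix, rose by 6.03, as did Igf2, an imprinted growth factor. Usp17la, a deubiquitinase gene, rose by 5.77. Hoxa9 rose by 5.72 ± 0.78 (SE, limma adjusted p = 7.0e-07), against 2.99 with the array set as a block. In the genes that follow, the 8 h mean lay under the lower quartile of every array. Hoxc10, a posterior Hox gene on chromosome 15, with an 8 h mean of 3.84, rose by at least 6.24 (limma adjusted p = 4.7e-15). Epha3, an ephrin receptor, with 2.97, rose by at least 6.10 (limma adjusted p = 1.6e-17). Hoxc8, with 4.36, rose by at least 6.10 (limma adjusted p = 4.6e-11) and Zic1, with 4.17, by at least 5.72 (limma adjusted p = 2.9e-14).

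Trh fell by 3.94 ± 0.13 from 8 h to 72 h (SE, limma adjusted p = 3.0e-18). Utf1, a chromatin factor of stem cells, fell by 3.19 ± 0.11 (SE, limma adjusted p = 2.7e-17). Otx2 fell by at least 3.87, to a mean of 4.49, and Inhbb fell by 3.88, against -2.16 and -2.23 with the array set as a block. Chac1, a glutathione-degrading enzyme of the stress response, fell by 3.28 and Slc7a3, a transporter of cationic amino acids, fell by 3.14. Mt4, a metallothionein, fell by 3.41 with -1.36 in the fit with the set as a block, and Liph, a lipase, fell by 3.11 with -1.39. In each gene of the 10 rises and 10 falls, all 72 h arrays lay beyond all 8 h arrays.

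By 72 h the retinoic acid list rose, with 15 of 24 members higher and 6 lower, also adjusted over the list alone, a median of 0.88, a camera adjusted p of 5.49e-05 and adjusted p = 0.0484 with an estimated correlation. Nr2f2, an orphan nuclear receptor, rose by 5.37 and Rarb, an RA receptor whose gene RA induces, by 3.34. Anterior Hox genes rose, 10 of 10 higher and 0 lower, also adjusted over the list alone, with a median of 2.40 and a camera adjusted p of 6.56e-07 (adjusted p = 0.0777 with an estimated correlation). Of these, Hoxa4 and Hoxb1 had 0.43 and 0.30 with the array set as a block and were not called there. Central Hox genes rose, 8 of 9 higher and 0 lower (8 and 1 adjusted over the list alone), with a median of 2.73 and a camera adjusted p of 1.90e-05 (adjusted p = 0.0684 with an estimated correlation). Posterior Hox genes rose, 9 of 14 higher and 1 lower, also adjusted over the list alone, with a median of 0.72, a camera adjusted p of 0.000253 and adjusted p = 0.0484 with an estimated correlation. Hoxa10, on an _a_at probe set, had at least 3.73 in the fit of all arrays. It had -0.03 on another probe set, used where that type was left out. TALE cofactors rose, 5 of 8 higher and 0 lower, also adjusted over the list alone, with a median of 1.29 and a camera adjusted p of 0.00507 (adjusted p = 0.0684 with an estimated correlation, and 0.0728 with the preset one where cross-hybridising probe types were left out). Pluripotency genes fell, 28 of 31 lower and 1 higher (28 and 2 adjusted over the list alone), with a median of -1.59, a camera adjusted p of 1.52e-11 and adjusted p = 0.0484 with an estimated correlation. Tdgf1, a Nodal co-receptor, fell by 3.01 and Eras, a Ras of stem cells, fell by 2.89. Neural genes rose, 18 of 28 higher and 3 lower, also adjusted over the list alone, with a median of 0.81, a camera adjusted p of 6.05e-06 and adjusted p = 0.0484 with an estimated correlation, Lhx1 by 4.60 and Ncam1, a neural adhesion molecule, by 3.60.

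Genes of embryonic fibroblasts rose at 72 h, with 28 of 30 higher and 0 lower, also adjusted over the list alone, a median of 2.45 and a camera adjusted p of 5.12e-13 (adjusted p = 0.0684 with an estimated correlation). Acta2, smooth muscle actin, rose by 4.95, and the collagen genes Col3a1 and Col1a1 rose by 4.29 and 4.23. Endoderm genes rose beside them, with 19 of 26 higher and 2 lower (19 and 3 adjusted over the list alone), a median of 1.96 and a camera adjusted p of 1.61e-08 (adjusted p = 0.0684 with an estimated correlation). Plat, tissue plasminogen activator, rose by 4.42, Sox17 by 4.00 and the basement membrane collagen Col4a1 by 3.11. Mesoderm genes rose, 11 of 21 higher and 4 lower, also adjusted over the list alone, with a median of 0.26 and a camera adjusted p of 0.00507 (adjusted p = 0.0774 with an estimated correlation), Foxc2 by 4.32 and Hand2 by 4.01. Trophoblast genes rose, 8 of 15 higher and 2 lower, also adjusted over the list alone, with a median of 0.93 and a camera adjusted p of 0.00198 (adjusted p = 0.106 with an estimated correlation), Gata3 by 4.13 and Krt18, a keratin of simple epithelia, by 2.79. The two-cell-like list rose, 4 of 6 higher and 1 lower, also adjusted over the list alone, with a median of 2.80 and a camera adjusted p of 0.00788 (adjusted p = 0.166 with an estimated correlation). That list had adjusted p = 0.0799 where dim genes were left out.

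The p53 response list rose at 72 h, with 11 of 16 higher and 2 lower, also adjusted over the list alone, a median of 0.34 and a camera adjusted p of 0.00291 (adjusted p = 0.0684 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 1.48. Immediate early genes rose, 9 of 17 higher and 1 lower, also adjusted over the list alone, with a median of 0.48 and a camera adjusted p of 0.00507 (adjusted p = 0.173 with an estimated correlation), Ccn1 by 2.73 (1.72 with the array set as a block). Over the 9 arrays from 48 h to 72 h, the deviations of this list from its time means were compared with those of the fibroblast list. The relation did not pass after adjustment, with r = 0.859 and rho = 0.733 (exact permutation p = 0.0370 and 0.0648), r = 0.883 without the 2 farthest arrays and adjusted p = 0.272 over 22 lists. In that permutation test a single list cannot get below an adjusted p of 0.102, so the failure says little against the relation. Glycolysis genes fell, 12 of 19 lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.28 and a camera adjusted p of 0.0491. The glycolysis call was lost with an estimated correlation (adjusted p = 0.629), with the array set as a block (0.343), where the table was quantile normalised again (0.0675), and without 8 h C (median -0.25), 72 h B (-0.26) or 72 h C (-0.31). Egln3, an oxygen-sensing hydroxylase, fell by 2.92, with -1.38 in the fit with the set as a block. The other 8 lists did not pass camera at 72 h. The adjusted p was 0.420 for formative and primed epiblast, 0.620 for germ cell, for heat shock and unfolded protein and for housekeeping reference, 0.0522 for cell cycle, 0.0536 for Nodal, BMP and TGF-beta, 0.571 for Wnt, FGF and hedgehog and 0.0599 for cholesterol synthesis. Cell cycle genes had 16 of 25 lower and 2 higher (16 and 4 adjusted over the list alone) and passed with the array set as a block (median -0.20, adjusted p = 0.00542), without 8 h B (0.0488) or 72 h A (0.0439), and with dim genes left out, array weights or the mean of all probe sets (0.0429 to 0.049993). Nodal genes passed upward under 6 alternatives, among them a fit of the 8 h and 72 h arrays alone (adjusted p = 0.0148) and leaving out 8 h C (0.0396). Cholesterol genes passed upward under 4, the fit of these 2 groups alone (adjusted p = 0.00466), arrays A to C at 12 h and 24 h (0.00581), the replicate letter as a block (0.00975) and array weights (0.0342). The relation of Nodal genes to the fibroblast list over these 9 arrays did not pass after adjustment either, with r = 0.794 and rho = 0.817 (exact permutation p = 0.0278 and 0.0417), r = 0.778 without the 2 farthest arrays and adjusted p = 0.272 over 22 lists. The limit on the adjusted p holds for Nodal genes too, and their exact p also lay above the smallest possible. Fst, a secreted activin antagonist of the Nodal list, rose by 5.04, Gli1, a hedgehog target, fell by 2.72 and Cdh2, N-cadherin, rose by 4.32, against 2.57 with the array set as a block. In the germ cell list the median was 0.16 with a mean of -0.00, and among reference genes B2m, a subunit of MHC class I, rose by 2.00 while Hprt fell by 0.83.

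Between 8 h and 72 h, limma called 10601 genes, 4308 higher and 6293 lower, and 2144 changed by at least 1 log2, of which 1532 were higher and 612 lower. With the array set as a block 9860 were called (4696 higher, 5164 lower), 7972 of them among the 10601 and 7970 with the same sign. Set 2 alone, which holds no 8 h array, gave 10471 genes between 12 h and 72 h, 4522 higher and 5949 lower.

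**Figure D3:**
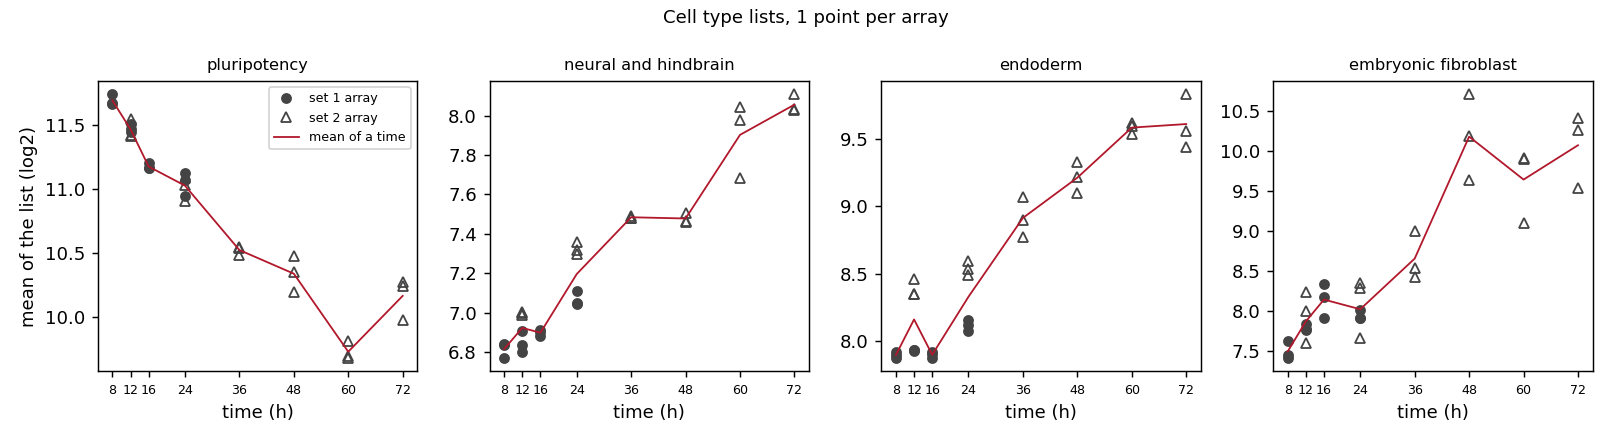
Mean log2 of the measured genes of 4 lists (pluripotency, neural and hindbrain, endoderm, embryonic fibroblast; y axes differ) on each array against time (h), with filled circles for set 1, open triangles for set 2 and a red line through the mean of each time. The fibroblast list has its largest rise between neighbouring times from 36 h to 48 h, by a median of 1.58.

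At the other times after 8 h, Crabp2 rose by 3.18 ± 0.16 at 16 h (SE, limma adjusted p = 1.3e-12), Hoxb6 rose by 3.04 and Chac1 fell by 2.35, with all 16 h arrays beyond all 8 h arrays. Pdzrn3, a ubiquitin ligase, rose by 2.38 on an _a_at probe set, against 0.06 on its other probe set. Immediate early genes fell at 16 h, 11 of 17 lower and 0 higher, also adjusted over the list alone, with a median of -0.76, a camera adjusted p of 5.49e-07 and adjusted p = 0.113 with an estimated correlation, Myc by -1.79 and Atf3 by -1.73. Pluripotency genes fell, 17 of 31 lower and 0 higher (18 and 0 adjusted over the list alone), with a camera adjusted p of 2.70e-07 (adjusted p = 0.123 with an estimated correlation). Fibroblast genes rose beside them, 7 of 30 higher and 0 lower, also adjusted over the list alone, with a median of 0.65 and a camera adjusted p of 0.00291 (adjusted p = 0.589 with an estimated correlation). Within set 1, 23 of 30 were higher and 1 lower, with a camera adjusted p of 1.04e-05. By limma 5671 genes were called at 16 h, 3404 higher and 2267 lower, and 8589 in set 1 alone.

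At 36 h against 8 h, Hoxc5 rose by at least 5.53 ± 0.39 (SE, limma adjusted p = 2.3e-11), Hoxc8 by at least 5.37 and Hoxb6 by 5.14, while Inhbb fell by 4.99, Otx2 fell by at least 4.06 and Chac1 fell by 3.17, with all 36 h arrays beyond all 8 h arrays. Inhbb and Otx2 had -3.34 and -2.35 with the array set as a block. All 13 measured cholesterol genes rose, also adjusted over the list alone, with a median of 0.81 and a camera adjusted p of 2.91e-06, against a median of 0.38 with the set as a block and adjusted p = 0.218 with an estimated correlation. Two-cell-like genes rose, 4 of 6 higher and 1 lower, also adjusted over the list alone, with a median of 1.33 and a camera adjusted p of 0.0334 (adjusted p = 0.248 with an estimated correlation, and 0.130 with the set as a block). By limma 8160 genes were called at 36 h, 1319 of them by at least 1 log2 (994 higher, 325 lower). Of all called genes 47.6% were higher, against 58.4% of 7309 with the array set as a block.

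At 48 h and 60 h against 8 h, Hoxc8 rose by at least 6.09 and 6.69 (SE 0.48 each, limma adjusted p = 9.0e-11 and 7.9e-12). Fbn2 and Pmp22, a myelin protein, rose by 5.30 and 5.29 at 48 h, and Nr2f1 rose by 6.62 at 60 h. Otx2 fell to means of 4.33 at 48 h and 4.16 at 60 h, by at least 4.03 and at least 4.20. The 2 times have no order there. Inhbb fell by 3.62 at 48 h, against -1.97 with the array set as a block, where Otx2 had -2.32 at 48 h and -2.49 at 60 h. All arrays of the later time lay beyond all 8 h arrays for these genes. Fibroblast genes rose at 48 h, 30 of 30 higher and 0 lower, also adjusted over the list alone, with a median of 2.62 and a camera adjusted p of 2.24e-17 (adjusted p = 0.0620 with an estimated correlation). Pluripotency genes fell at 60 h, 29 of 31 lower and 1 higher, also adjusted over the list alone, with a median of -1.98, a camera adjusted p of 4.92e-15 and adjusted p = 0.0249 with an estimated correlation. Fibroblast genes rose beside them, 25 of 30 higher and 0 lower (27 and 0 adjusted over the list alone), with a median of 1.97 and a camera adjusted p of 1.30e-11 (adjusted p = 0.0821 with an estimated correlation). By limma 8791 genes were called at 48 h (3795 higher, 4996 lower) and 10091 at 60 h (3909 higher, 6182 lower). With the set as a block they were 7836 at 48 h, 3965 higher and 3871 lower, so that the majority turned, and 9332 at 60 h, 4257 higher and 5075 lower.

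Neighbouring times show what changed step by step. From 12 h to 16 h, Crabp2 rose by 1.96 ± 0.14 (SE, limma adjusted p = 3.6e-09) and Myc, a growth-promoting transcription factor, fell by 1.88 ± 0.34 (SE, limma adjusted p = 0.00025), with -1.28 with the array set as a block. All 16 h arrays lay beyond all 12 h arrays for both. Immediate early genes fell, 11 of 17 lower and 0 higher (12 and 0 adjusted over the list alone), with a median of -0.66 and a camera adjusted p of 1.41e-06 (adjusted p = 0.131 with an estimated correlation). Wnt, FGF and hedgehog genes fell, 8 of 23 lower and 1 higher, also adjusted over the list alone, with a camera adjusted p of 0.00158 (adjusted p = 0.167 with an estimated correlation), Spry4, an FGF feedback inhibitor, by -1.47. Within set 1 the mean of the fibroblast list lay higher at 16 h, at 7.91 to 8.33 against 7.76 to 7.83 at 12 h. By limma 5210 genes were called, 2984 higher and 2226 lower.

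From 16 h to 24 h, immediate early genes rose, 13 of 17 higher and 0 lower, also adjusted over the list alone, with a median of 0.97, a camera adjusted p of 1.03e-12 and adjusted p = 0.00406 with an estimated correlation. Egr1 rose by 2.12, Atf3 by 1.96 and Jun by 1.91. The p53 response list rose, 9 of 16 higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.41, a camera adjusted p of 5.63e-07 and adjusted p = 0.00406 with an estimated correlation. Heat shock and unfolded protein genes rose, 7 of 14 higher and 1 lower, also adjusted over the list alone, with a camera adjusted p of 0.00167 and adjusted p = 0.0143 with an estimated correlation. Cell cycle genes fell, 12 of 25 lower and 1 higher (16 and 2 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 0.000636 (adjusted p = 0.143 with an estimated correlation). Car3, carbonic anhydrase, rose by 2.45 ± 0.47 (SE, limma adjusted p = 0.00037), with 1.53 with the array set as a block, and Sh2d5 fell by 1.92 ± 0.17 (SE, limma adjusted p = 2.3e-08). All 24 h arrays lay beyond all 16 h arrays for both. By limma 5341 genes were called, 2431 higher and 2910 lower, against 2461 higher and 2424 lower with the array set as a block.

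From 24 h to 36 h, Hoxc8 rose by 3.70 ± 0.42 (SE, limma adjusted p = 1.4e-06) and Hoxc10 by 2.76 ± 0.26 (SE, limma adjusted p = 1.6e-07), while Chac1 fell by 2.34, Inhbb fell by 2.07 and Otx2 fell by at least 2.02. Inhbb and Otx2 had -1.25 and -1.16 with the array set as a block, and Otx2 was not called in a fit of these 2 groups alone. All 36 h arrays lay beyond all 24 h arrays for these genes. Endoderm genes rose, 15 of 26 higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 0.51 and a camera adjusted p of 1.61e-07 (adjusted p = 0.100 with an estimated correlation). By limma 2815 genes were called, 1638 higher and 1177 lower, against 1584 in set 2 alone, and 1870, 1724 and 1606 without 36 h A, B and C.

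From 36 h to 48 h, fibroblast genes rose, 26 of 30 higher and 0 lower (27 and 0 adjusted over the list alone), with a median of 1.58, a camera adjusted p of 3.68e-29 and adjusted p = 0.0352 with an estimated correlation. Ogn, a matrix protein of that list, rose by 2.46 ± 0.47 (SE, limma adjusted p = 0.0011), Inhba, an activin subunit, by 2.41 and Olr1, a scavenger receptor, by at least 2.36. Egr2, a hindbrain transcription factor, fell by 2.04 ± 0.19 (SE, limma adjusted p = 8.9e-08) and Pou3f1, a factor of the epiblast and neural plate, fell by 1.77 ± 0.14 (SE, limma adjusted p = 6.8e-09). All 48 h arrays lay beyond all 36 h arrays for these genes. Anterior Hox genes fell, 3 of 10 lower and 0 higher (5 and 0 adjusted over the list alone), with a median of -0.67 and a camera adjusted p of 0.00773 (adjusted p = 0.453 with an estimated correlation), with a change of -0.99 in Hoxb1. By limma 1821 genes were called, 712 higher and 1109 lower, against 3332 with the array set as a block and 3054 in set 2 alone. The count was 1093 without 36 h A, 945 without 36 h B, 1189 without 48 h A and 888 without 48 h C.

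From 48 h to 60 h, pluripotency genes fell, 21 of 31 lower and 0 higher (22 and 0 adjusted over the list alone), with a median of -0.64, a camera adjusted p of 2.80e-16 and adjusted p = 0.0171 with an estimated correlation. Neural genes rose, 13 of 28 higher and 2 lower (15 and 4 adjusted over the list alone), with a median of 0.40, a camera adjusted p of 3.03e-08 and adjusted p = 0.0193 with an estimated correlation. Fibroblast genes had 4 of 30 lower and 2 higher (6 and 2 adjusted over the list alone), a median of -0.51 and a camera adjusted p of 0.00305 (adjusted p = 0.539 with an estimated correlation). Epha3 rose by 2.66 ± 0.21 (SE, limma adjusted p = 5.9e-09) and Mir124-2hg, the host gene of a neuronal microRNA, by at least 2.66 ± 0.18 (SE, limma adjusted p = 2.3e-10). Lefty2, a Nodal antagonist, fell by 1.77 ± 0.23 (SE, limma adjusted p = 1.3e-05). All 60 h arrays lay beyond all 48 h arrays for these 3 genes. By limma 1827 genes were called, 785 higher and 1042 lower, against 3443 with the array set as a block and 3128 in set 2 alone. The count was 1166 without 48 h B, 1125 without 48 h C, 1013 without 60 h A and 910 without 60 h B.

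From 60 h to 72 h, Fabp7, a fatty acid carrier of radial glia, rose by 1.85 ± 0.26 (SE, limma adjusted p = 0.00011) and Nefm, a neurofilament, by 1.82 ± 0.29 (SE, limma adjusted p = 0.00048), the latter not called in a fit of these 2 groups alone. Apoa2, an apolipoprotein, fell by 1.86 ± 0.22 (SE, limma adjusted p = 7.8e-06), also not called there, and Aldh1a7 fell by 1.69. All 72 h arrays lay beyond all 60 h arrays for these 4 genes. Pluripotency genes rose, 12 of 31 higher and 0 lower (19 and 1 adjusted over the list alone), with a median of 0.39, a camera adjusted p of 4.68e-12 and adjusted p = 0.0648 with an estimated correlation. Fibroblast genes moved in the same step, 1 of 30 higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.48 and a camera adjusted p of 0.00373. It was 0.0164 in set 2 alone, and adjusted p = 0.621 with an estimated correlation. Anterior Hox genes had 2 of 10 lower and 0 higher (3 and 0 adjusted over the list alone), a median of -0.15 and a camera adjusted p of 0.00813. That was 0.000380 in set 2 alone, and adjusted p = 0.619 with an estimated correlation. Central Hox genes did not pass (median -0.55, camera adjusted p = 0.0548) except in set 2 alone (0.000352). The p53 response list rose, 3 of 16 higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.00105 (adjusted p = 0.0711 with an estimated correlation). The Wnt list rose, 3 of 23 higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.25 and a camera adjusted p of 0.0168 (adjusted p = 0.304 with an estimated correlation). By limma 518 genes were called, 415 higher and 103 lower, against 1355 with the array set as a block and 1037 in set 2 alone. The count was 228 without 60 h A, 240 without 60 h B, 940 without 60 h C, 310 without 72 h B and 245 without 72 h C.

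The order in which Hox genes rose was compared with their paralogue number, which follows their place in each cluster. The first time with a called rise of at least 1 log2 was 12 h for 10 genes, among them Hoxb1, Hoxb2, Hoxa3 and Hoxb9, 16 h for 4, 24 h for 5 and 36 h for 6, among them Hoxc9, Hoxd9 and Hoxd3. In that fit of all arrays without a block, no gene had its first such rise later, and 8 had none, among them Hoxd11, Hoxd12, Hoxc13 and Hoxa13, of which Hoxd11, Hoxd12 and Hoxa13 had means under 4.73 at every time. Over the 25 genes with such a rise, Spearman's rho was 0.427 (two-sided permutation test, p = 0.0346), a relation across genes, which are not independent replicates. The test no longer passed with the mean of all probe sets of a gene (rho = 0.382, p = 0.0612), without cross-hybridising probe types (0.372, p = 0.0805), with arrays A to C alone at 12 h and 24 h (0.366, p = 0.0732), or without 8 h A (0.389), 12 h D (0.396) or 12 h E (0.396). With the array set as a block rho was 0.465, again past the threshold, and the first time moved from 12 h to 16 h for Hoxa3, Hoxa5, Hoxb4 and Hoxb9 and to 24 h for Hoxa4. In that fit it also moved from 24 h to 16 h for Hoxa9, to 36 h for Hoxc10 and to 72 h for Hoxa10, and Hoxa7 had no such rise.

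**Figure D4:**
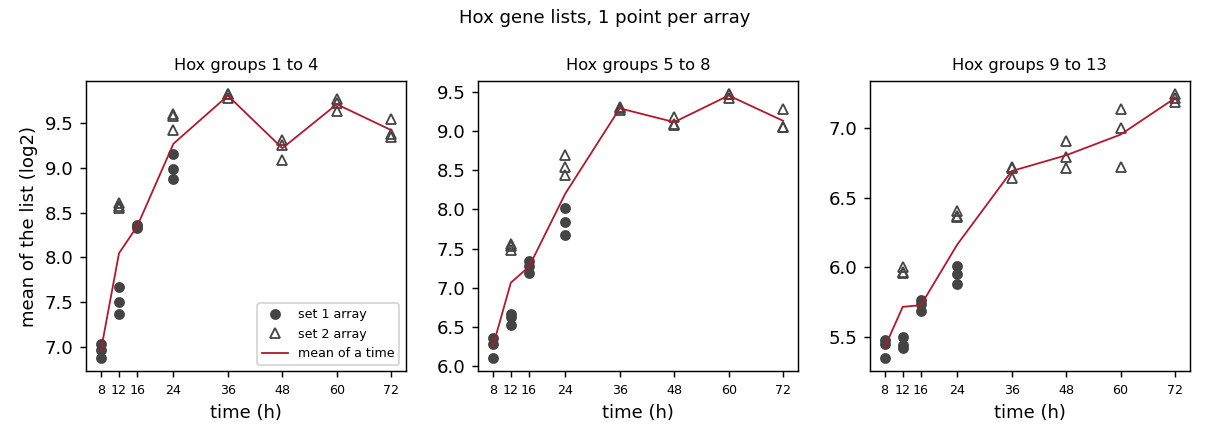
Mean log2 of the measured Hox genes of paralogue groups 1 to 4, 5 to 8 and 9 to 13 (3 panels; y axes differ) on each array against time (h), with filled circles for set 1, open triangles for set 2 and a red line through the mean of each time. At 12 h the D to F arrays lie above the A to C arrays in each panel, by a median of 1.26 over the genes of groups 1 to 4.

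The mean level of the 30 fibroblast genes was compared because the cells were grown on feeders. This level gives neither an amount of feeder RNA nor the source of the transcripts. It was 7.49 ± 0.12 (SD, n = 3) at 8 h and 7.87 ± 0.22 (SD, n = 6) at 12 h, a difference of 0.38 (two-sided exact permutation test, p = 0.0595), with 5 of 6 arrays above all 8 h arrays. Without 12 h E the difference was 0.43 and its exact p 0.0179. At 24 h it was higher than at 8 h by 0.53 (exact permutation p = 0.0238) in 6 of 6 arrays, and the exact p rose above the threshold without 8 h A (0.49), 8 h C (0.51), 24 h B (0.53) or 24 h E (0.48). Arrays A to C gave 0.45 and D to F 0.61, each at an exact permutation p of 0.1, the smallest that 3 against 3 allow. At 72 h the level was 10.07 ± 0.47 (SD, n = 3), higher than at 8 h by 2.58 in 3 of 3 arrays, and within set 2 higher than at 12 h by 2.13, each again at the smallest exact permutation p, 0.1.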

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

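The test of arrays D to F as further along the time course was chosen after the result was seen, and the array sets themselves were found in the data.

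Crabp2 at 12 h was lowest in replicate A, at 9.73 against 10.23 to 10.51 in the other 5 arrays. The gap to its neighbour was 0.642 of the whole range, above Dixon's critical ratio for 6 samples. It was the 1 group past that ratio out of 110 tested, and chance alone passes about 1 group in 20.

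The change from 12 h to 24 h differed between arrays A to C and arrays D to F in 3495 genes by limma's interaction test. The letters differed in 3432 genes at both times, 3089 of them in the same direction, with r = 0.584 between the 2 differences across all genes, which are not independent replicates. A constant technical difference between the array sets is argued against as the whole cause, since 19.2% of genes passed the interaction test, above the bound of 5 percent set in advance. D to F cultures being further along the course stays open, since the 12 h difference and the change from 8 h to 24 h within set 1 had r = 0.105 across the genes that differ at 12 h, between the bounds of 0.3 for it and 0.1 against it, although only 43.9% of those genes had the same sign in both, which goes against it. A technical difference whose size varies with time, or cultures grown apart, may also contribute, and neither was tested.

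Among 9160 probe sets with no gene symbol, which the comparisons leave out, limma called 3171 between 8 h and 72 h (34.6%), 1062 higher and 2109 lower. With no control samples in the series, no explanation was tested for them.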

How the results depend on the processing

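The fits with the array set as a block, set 1 arrays only and set 2 arrays only were chosen after the data were seen. Centring or quantile normalising the arrays again, leaving out dim genes and the trend and robust prior kept all 19 summary results on their side of the threshold or within 1.5 times. So did the other onset definitions for the Hox order (rho = 0.546, 0.674 and 0.430) and the fibroblast members above the median for the 3 fibroblast levels. Over all alternatives, 360 values of summary results were the same and 67 changed, and 6578 values of named genes kept their call, 338 lost it and 5 reversed. For gene lists, 1349 values kept their call or lack of one, 67 lost it, 51 gained it and 5 reversed, and 31 counts at 1 log2 moved while 219 did not. Except where fewer arrays were fitted, the cause was not tested.

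Genes called with array weights were 1663 at 12 h, 9088 at 16 h (both against 8 h), 2978 at 48 h against 36 h, 5564 at 60 h against 48 h and 3930 at 72 h against 60 h. With only the 2 groups compared in the fit they were 400 and 8623 at 12 h and 16 h against 8 h, 3238 at 16 h against 12 h, 1589 at 36 h against 24 h, 813 at 60 h against 48 h and 131 at 72 h against 60 h. With only arrays A to C they were 3346 at 12 h against 8 h, and 7351, 3797, 3987 and 1787 over the steps from 24 h on. With only arrays D to F they were 5292 at 12 h against 8 h, 8849 at 16 h against 12 h and 8016 at 24 h against 16 h. With the replicate block they were 1781 at 12 h against 8 h, and 6955, 3197, 3358 and 1362 over the steps from 24 h on. The labels do not say what the letters mark. In the replicate block check, 25 of 87 pairs with the same letter had r over 0.1 (-0.351 to 0.621, median 0.03, against -0.005 for other letters). The check used deviations from time means, which at 12 h and 24 h carry the difference of A to C from D to F. It therefore cannot decide whether letters mark pairs. With the array set as a block the genes called were 1923 at 12 h against 8 h, and 3332, 3443 and 1355 over the steps from 36 h on. In set 1 alone they were 4324 and 8589 at 12 h and 16 h against 8 h, and in set 2 alone 1584, 3054, 3128 and 1037 over the steps from 24 h on.

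The Hox order lost its call with the mean of all probe sets (0.382), without cross-hybridising types (0.372) and with only arrays A to C (0.366). The fibroblast level at 24 h lost it with only arrays A to C (0.453) or D to F (0.605), where 3 against 3 arrays cannot pass. With an estimated correlation 7 list tests passed in place of 33.

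Values that reversed were Hoxd13 at 72 h with the mean of all probe sets (-0.0410), and Ccng1 and Hoxa10 without cross-hybridising types (-0.26 and -0.21 at 24 h, -0.629 and -0.0335 at 72 h). At 12 h these were glycolysis with only arrays A to C or set 1 (0.16 each), immediate early with only arrays D to F (-0.0931, where the test turned upward) and cholesterol synthesis with the replicate block or the array set as a block (-0.0797 each).

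Leaving out 1 array gave counts against 8 h of 320 to 1037 at 12 h, 4577 to 4692 at 16 h, 4288 to 5884 at 24 h, 6821 to 7336 at 36 h, 7528 to 8065 at 48 h, 8782 to 9925 at 60 h and 9338 to 9694 at 72 h. Step by step they were 3652 to 5844 (12 h to 16 h), 3836 to 5513 (16 h to 24 h), 1606 to 3532 (24 h to 36 h), 888 to 1762 (36 h to 48 h), 910 to 2210 (48 h to 60 h) and 228 to 940 (60 h to 72 h). The whole course gave 13288 to 14004, the lists 32 to 36, the Hox order 0.389 to 0.512, and the fibroblast level 0.302 to 0.442 at 12 h, 0.464 to 0.600 at 24 h and 2.41 to 2.85 at 72 h.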

Other observations

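The test of fibroblast genes that rose from 48 h to 60 h, and the test of the two-cell-like list within set 2, were chosen after the result was seen, as were the separate tests of Xist against the mean of the fibroblast members.

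Other gene groups changed at times that the report describes briefly. Endoderm genes rose at 48 h against 8 h, 20 of 26 higher and 2 lower (20 and 3 adjusted over the list alone), with a median of 1.40 and a camera adjusted p of 3.96e-08 (adjusted p = 0.0698 with an estimated correlation). Two-cell-like genes rose at 60 h against 8 h, 5 of 6 higher and 1 lower, also adjusted over the list alone, with a median of 3.38 and a camera adjusted p of 0.00352 (adjusted p = 0.124 with an estimated correlation). Cholesterol synthesis genes fell from 36 h to 48 h, 6 of 13 lower and 0 higher (7 and 0 adjusted over the list alone), with a median of -0.37 and a camera adjusted p of 0.000183 (adjusted p = 0.453 with an estimated correlation).

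The fibroblast list passed camera against 8 h at each later time, a call lost with an estimated correlation (adjusted p = 0.550 at 12 h, 0.589 at 16 h, 0.413 at 24 h, 0.235 at 36 h, 0.0620 at 48 h, 0.0821 at 60 h and 0.0684 at 72 h), its mean level at 12 h had an exact permutation p of 0.0595, and its rise from 36 h to 48 h, by a median of 1.58, held (adjusted p = 0.0352 with an estimated correlation). Feeder cells carried into the lysate are a candidate source for part of it, since the protocol names a replating step and the labels leave open which cells it kept. Feeders alone are argued against for Mmp2 and Twist1, as these 2 genes were called higher from 48 h to 60 h (1.04 and 0.59) while Thy1, Thbs2 and Col6a2 were called lower (-1.29, -1.11 and -0.78), as was Aspn at a level under the lower quartiles of the arrays. For the other 28 members the values that feeders need are there, as their deviations from the time means at 48 h, 60 h and 72 h, over 9 arrays, had a mean pairwise r of 0.696, against a median of 0.07 and a 95th percentile of 0.18 over 1000 random lists. The labels give the sex of neither feeders nor stem cells, so fibroblast-like cells arising in the culture, which could vary between dishes too, stay open beside feeders, and no test separated the 2 sources.

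Xist, the RNA that silences an X chromosome in female cells, was named in advance as following the list if the feeders held female cells, and the 28 members had a mean r of 0.789 with its deviations over these arrays. The deviations of Xist from its time means were also compared with those of the mean of the 28 members, by exact permutation within times (2 relations). Over the 9 arrays Pearson's r was 0.936 (exact permutation p = 0.00926, adjusted p = 0.00926), Spearman's rho 0.933 (exact permutation p = 0.00926) and r without the 2 farthest arrays 0.911. Over the 18 arrays of set 2 r was 0.897 (exact permutation p = 0.000171, adjusted p = 0.000343), rho 0.928 (exact permutation p = 0.000300) and r without the 2 farthest arrays 0.856. Xist was measured on a probe set of a type that can cross-hybridise. The abundant members Tagln, Acta2 and Col3a1 had means of 9.81, 9.10 and 9.01 at 8 h and of 13.48, 14.05 and 13.3 at 72 h.

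Over the same 9 arrays, the deviations of each of the other 22 lists from their time means were compared with those of the fibroblast list, by exact permutation within times. The strongest relation was that of the trophoblast list, with Pearson's r = -0.912 (exact permutation p = 0.00463, adjusted p = 0.102 over 22 lists), Spearman's rho = -0.950 (exact permutation p = 0.00463), and r = -0.855 without the 2 arrays farthest from the median. With 216 permutations the smallest exact p is 0.00463, and a single list cannot get below an adjusted p of 0.102, where the trophoblast list lies, so the adjusted test could not pass for 1 list alone and says nothing against that relation. The immediate early and Nodal lists had r = 0.859 and 0.794, and neither passed after adjustment (adjusted p = 0.272 each), as the report gives in full. The same limit applies to these 2 lists, but their exact p-values lay above the smallest possible, so it does not alone account for their failure.

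The two-cell-like list passed camera against 8 h from 36 h on, a call lost with an estimated correlation (adjusted p = 0.248 at 36 h, 0.239 at 48 h, 0.124 at 60 h and 0.166 at 72 h) and, at 36 h and 48 h, with the array set as a block (0.130 and 0.0773). Its later times lie in set 2 while 8 h lies in set 1, but values within set 2 argue against a difference between array sets as the whole cause. The list mean there was 5.81 to 6.00 at 12 h, 7.33 to 7.52 at 36 h and 7.34 to 7.75 at 48 h. These means were compared after the result was seen and without a test. Between 12 h and 72 h within set 2, 4 members were called higher, among them Usp17la (4.72) and Zfp352 (2.18). Tcstv1 (at least 4.52) and Tcstv3 (at least 3.18) rose from 12 h means under the lower quartiles of the arrays. Under cross-hybridisation within 1 gene family, the members called higher were predicted to lie on 1 chromosome, and these 4 lie on 3 (13, 7 and 4). A chromosome does not show what a probe set binds, so this test cannot decide. Cross-hybridisation stays open, also for Tcstv1 and Tcstv3, which share chromosome 13. Of the other measured members, Eif1a fell by 0.31 there and Tdpoz1 did not pass. A shift of some cells to such a state remains a hypothesis, since 8 of the 14 fixed members were not measured.

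Other splits of the samples were fitted with limma for each count of called genes. For the whole time course, 1 of 100 splits, the real one, called as many as 13816 genes, and the highest other called 2063. That share lies under 0.05, the bound set in advance. These splits exchanged arrays between the 2 array sets as well as between times. A difference between the sets could therefore also put the real split first, and the share draws no line between the 2. The share lay under 0.05 too at 24 h against 8 h (5849 genes, 1 of 84 splits, highest other 4656) and at 24 h against 16 h (5341 genes, 1 of 84, highest other 5148). In both, that highest split set 24 h D to F against the rest. At 12 h against 8 h, 3 of 84 splits called at least the 901 of the real one, a share under 0.05. Of these, 12 h D to F against the rest called 5311, a split that follows the array set and points to a structure of the samples. With the set as a block 1923 genes were called. At 16 h against 12 h, 2 of 84 splits called as many as 5210 genes, the other being 12 h D to F against the rest with 7451, and 4638 were called with the set as a block. At 36 h against 24 h, 2 of 84 called as many as 2815, the other being 24 h A to C against the rest with 5922, and 2699 were called with the set as a block. The share lay under 0.05 for both, and both of these splits follow the array set, as do those at 24 h against 8 h and 16 h. Arrays of 12 h and 24 h were therefore not exchangeable. The shares of the comparisons that use them, also not adjusted over comparisons, do not exclude chance.

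The other comparisons have 10 splits each, too few for a share under 0.05, and in each the real split was the 1 with the most genes by limma. Against 8 h, the real counts at 16 h, 36 h, 48 h, 60 h and 72 h were 5671, 8160, 8791, 10091 and 10601, and the highest other called 0. The count at 48 h against 36 h was 1821 with a highest other of 0, that at 60 h against 48 h was 1827 with 12, and that at 72 h against 60 h was 518 with 27.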
